A study of Mus musculus with 4 samples.

How the data were processed

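Total RNA from 4 clonal derivatives of c17.2, an immortalised mouse neural stem cell line, had been labelled with biotin and hybridised to Affymetrix mouse arrays, 1 array per clone. Clone 42 and clone 48 were stably transfected with the nuclear receptor Nurr1, and puroB and puroD with the empty puromycin vector. Per the labels, clone 42 was matched with puroB and clone 48 with puroD because they proliferated at similar rates. The series' design text writes the number of clone 42 a second time beside puroD, with the abbreviation of clone 48, and the sample descriptions were followed, which pair clone 48 with puroD. The clones are the replicates (2 per group), and their number limits the precision. With the pair in the fit, the p-values rest on how far the differences of the 2 matched pairs disagree. This spread is pooled with that of all tested probe sets, which carry most of its weight.

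The deposited values are linear intensity values, 1 signal per probe set and array, over 12469 rows. MAS5, Affymetrix's algorithm that combines the probe pairs of a probe set into 1 signal, is named in the submitters' processing notes; its version and scaling target, and detection calls, are not given in the sources used here. The values themselves show that each array had been scaled, because their means after trimming 2% from each end lay between 500.4 and 500.5. No further normalization between arrays was recorded.

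Each array was rescaled here to a trimmed mean of 500, signals under the 30th percentile of all values (40.3) were set to that floor, and log2 was taken. The floor matters because MAS5 signals near background differ between arrays by large ratios. A fold against an array at the floor is a lower bound on the ratio of signals. Probe sets were tested where at least 2 of 4 arrays exceeded the median of all values (145.05), without the 66 array controls, which left 6419. Background can be read from the control probe sets for transcripts that were not spiked in, whose median lay between 6.0 and 9.0 on the 4 arrays and whose highest value was 62.7. On clone 42, puroB and puroD their highest values (62.7, 49.8 and 59.1) exceed the floor. A bound from the floor on these arrays therefore does not hold for the amount of transcript.

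Gene symbols came from the platform annotation paired with the probe sets, checked through Entrez identifiers against a RefSeq gene table of assembly GRCm38.p6, which was used for names only. Of 12403 gene probe sets, 10814 had 1 symbol, 396 had several and 1193 had none; no symbol needed an update. The tested set held 5820 probe sets with 1 symbol, for 4957 genes. No coordinates were used, because no genome was given with the probe sets. For genes named for their change over both pairs, other tested probe sets are given beside the named one; for list members the brightest probe set is used.

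Nurr1-labelled and control clones were compared with limma 3.58.1 in R 4.3.3: lmFit on log2 signals with the matched pair as a block, eBayes with an intensity trend and Benjamini-Hochberg adjustment, with a threshold of 0.05. The fit has 1 residual degree of freedom per probe set, to which the prior adds 13.1. The pairing comes from the labels. As a check, the deviations of same-pair arrays from their group means correlated with r = 0.19 across genes, which are not independent replicates. Single pairs of arrays, the 2 control clones and the 2 Nurr1-labelled clones were compared by log2 ratio and by the number of probe sets at 2-fold or more, with no p-value, since each clone has 1 array.

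Before the data were examined, 24 gene lists were fixed: NR4A receptors and RXR partners, dopaminergic neuron, neural stem and progenitor, neuronal differentiation, astrocyte, oligodendrocyte, fibroblast and mesenchymal, microglia and macrophage, endothelial, S phase and DNA replication, mitosis, D cyclins and cell cycle inhibitors, antioxidant and oxidative stress, apoptosis, Wnt pathway, growth factor and cytokine, axon guidance and cell adhesion, interferon response, retinoid pathway, heat shock and unfolded protein, cholesterol synthesis, glycolysis and hypoxia, mitochondrial respiration, and ribosomal protein genes. Each gene entered with its brightest tested probe set. The 22 lists with at least 2 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. The estimated correlation rests on the 1 residual degree of freedom. In single pairs a list's median was placed among 10000 random lists of its size matched on mean signal, as a description of those arrays.

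The rule for named genes was also fixed beforehand. It takes Nr4a2; up to 12 probe sets per direction that passed the test, filled up with probe sets of the largest smaller-of-both-pairs change; up to 4 members per list; and the 5 highest and 5 lowest ratios of each matched pair and of the control clones. Of the list members, the 3 of the largest change are named for lists that camera called, and the 2 of the largest change for others. Members that passed when adjusted over their list alone are also named, of which Snai2, Gdnf and Tgfb3 fall outside the rule and were chosen after their values were seen. The adjustment over a list alone takes no account of the number of lists. Passing it does not stand for a call over all tested probe sets.

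The procedure was tested on 10 simulated data sets of 6419 probe sets with 200 changed in each. It called 4.18% of 1.5-fold, 20.4% of 2-fold and 90.3% of 4-fold changes. Of the calls made there, 14.6% were unchanged probe sets, more than the adjusted threshold implies. In the list test, the shifted list was found in 10 of 10 simulations and 0 of 230 other lists were called. Genes were drawn there independently and without a pair effect, so false calls from correlated list members could not appear. In the data the estimated correlation of the lists that camera called lay between -0.09 (neural stem) and 0.51 (mitosis).

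Alternatives chosen before the data were examined were a fit without the pair, quantile normalization, the deposited values without rescaling, scaling to the median of bright probe sets, no floor or a floor at the median, no filter or a filter that asks for all 4 arrays above the median, no intensity trend, 1 probe set per gene, other fold thresholds, the crossed pairing, other list tests, and leaving out each clone in turn.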

Results

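Expression was measured in 4 clonal lines of c17.2 mouse neural stem cells, an immortalised line derived from neonatal cerebellum, grown under proliferating conditions. Of these, 2 lines (clone 42 and clone 48) had been stably transfected with Nurr1, the orphan nuclear receptor encoded by Nr4a2 and required for midbrain dopaminergic neurons, and 2 lines (puroB and puroD) with the empty vector. Each line was measured on 1 array. Median signals were 147.1 in clone 42, 125.6 in clone 48, 160.1 in puroB and 145.9 in puroD. The ratio of 3' to 5' signal of the actin control, a sign of RNA integrity, was 1.68 in clone 42 and 1.51 in its match puroB, and 2.41 in clone 48 and 2.0 in its match puroD. The same ratio for Gapdh was 0.935 and 0.859 in the first pair and 1.24 and 0.973 in the other, so that in both pairs the Nurr1-labelled clone had the higher ratio for both transcripts. Signals of different arrays correlated across genes with r between 0.919 (clone 42 with clone 48) and 0.950 (clone 48 with puroD).

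Nr4a2 itself, the transfected gene, was not higher in the Nurr1-labelled clones. Its probe set 92248_at gave signals of 320 in clone 42 and 206 in clone 48, against 485 in puroB and 254 in puroD. The log2 difference was -0.60 in the first pair and -0.30 in the other, with a mean of -0.45 ± 0.30 (SE, n = 2 clones per group; limma, Benjamini-Hochberg adjusted p = 0.871); without puroB the difference was 0.016. The other probe set, 92249_g_at, gave -0.98 and -0.91, with a mean of -0.95 ± 0.34 (limma adjusted p = 0.453, unadjusted 0.0151), so that the control-labelled array was the higher one in both pairs at both probe sets. The control clones differed from each other by 0.93 and 0.80 for these probe sets. Which part of the transcript the probes cover, and whether the transfected sequence holds it, is not given in the sources used here, so these values do not check the labels if the probes lie outside it. Because the measured direction goes against the label, the transfected lines are called Nurr1-labelled clones throughout, and each direction below is that of the labels.

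The comparison of Nurr1-labelled with control clones asks which transcripts differ between lines made to overexpress Nurr1 and their matched controls. Tnc, which encodes the extracellular matrix glycoprotein tenascin C, rose most: its signal (101993_at) was 1473 in clone 42 and 409 in clone 48, against 89.6 in puroB and 121 in puroD, or 16.4-fold and 3.38-fold higher in the matched pairs. Tubb3, the neuronal class of beta-tubulin, rose 3.75-fold and 3.20-fold (161612_f_at), and Glipr2, a Golgi-associated protein, 4.42-fold and 2.55-fold (104276_at). A probe set shared by 3 histone H2B genes (93833_s_at) rose 9.98-fold and 2.64-fold. Plec, the cytoskeletal linker plectin, fell 2.63-fold and 5.44-fold (103855_at), and Kifc1, a spindle kinesin, 3.21-fold in the pair of clone 48 (98471_f_at). For Kifc1 the control clones also differed, by 2.11-fold, with 342 in puroB and 719 in puroD, against 224 in clone 48. In clone 42 the Kifc1 signal, 54.7 against 342 in puroB, lay under the highest control for transcripts that were not spiked in on that array, 62.7, so the size of the fall there is not known. Col11a1, a chain of fibrillar collagen XI (100481_at), fell at least 7.72-fold in signal in the first pair, where clone 42 was at the floor, and 4.51-fold in the other. The floor lies under the same control level of 62.7, so the bound does not hold for the amount of transcript.

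These 7 of 6419 tested probe sets (4 higher, 3 lower) passed in limma, each with a Benjamini-Hochberg adjusted p of 0.0487, and each differed in the same direction in both pairs. Mean log2 changes were 2.90 ± 0.43 (SE, n = 2 per group) for Tnc, 2.36 ± 0.39 for the histone H2B probe set, 1.79 ± 0.31 for Tubb3, 1.75 ± 0.31 for Glipr2, -1.92 ± 0.32 for Plec, -2.16 ± 0.35 for Kifc1, whose size rests on the low signal in clone 42, and -2.56 ± 0.45 for Col11a1, which takes clone 42 at the floor. Unadjusted p-values under 0.05 were found for 474 probe sets, where 321 are expected by chance. In fits without the pair as a block the count was lower than that, at 287. Splitting the arrays into clone 42 and puroB against clone 48 and puroD gave 515 in such a fit. The remaining split gave 235. The brighter Tubb3 probe set gave 0.92 ± 0.31 (limma adjusted p = 0.371). A Tnc probe set too dim to be tested had signals of 108 in clone 42 and 43.7 in clone 48, against 9.99 in puroB and 15.4 in puroD. Both controls lay under the floor, so its log2 differences of 1.42 and 0.12 are lower bounds for the signals. They do not hold for the amount of transcript. Without the pair as a block 0 probe sets passed (287 at an unadjusted p under 0.05), as with quantile normalization (379), scaling to the median (465), no floor (473) or no filter (560). Leaving out the block, the floor or the filter could not move the log2 differences of Tnc, Tubb3 and Plec, whose signals all lay above the floor. With quantile normalization and scaling to the median they were 3.04 and 2.93 for Tnc, and 1.77 and 1.83 for Tubb3. For Plec they were -1.85 and -1.88. Adjusted p-values of these genes in limma ran from 0.0625 to 0.903 under the settings without a call. Leaving out clone 42, clone 48, puroB or puroD gave 17, 51, 0 and 2 calls, of which 2, 6, 0 and 1 were among the 7. Without clone 42 the calls kept were Tubb3 at 1.67 and Plec at -2.35, whereas Kifc1 was -1.15, Tnc 1.97, Glipr2 1.41 and Col11a1 -2.24. Without clone 48 the call of Plec was lost (-1.49). Without puroD the only call kept was that of Tnc, at 3.11. The 7 adjusted p-values lie just under the threshold. On simulated data 14.6% of the calls were false. That share depends on how many changes were planted there and on their size, which are not known for the data. It therefore does not give the share of false calls among these 7.

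**Figure D1:**
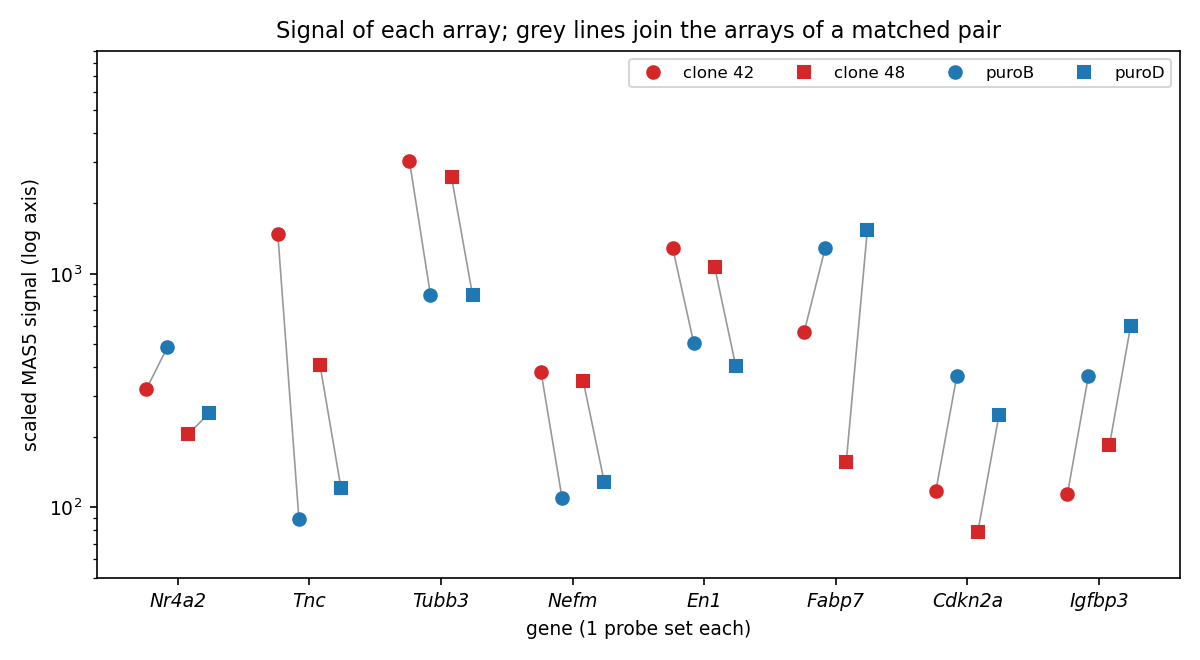
Scaled MAS5 signal (log axis) of 1 probe set each for 8 genes in the 4 arrays; red marks are the Nurr1-labelled clones, blue marks the controls, and grey lines join the arrays of a matched pair. Tnc, Tubb3, Nefm and En1 lie higher in the Nurr1-labelled array of both pairs and Fabp7, Cdkn2a and Igfbp3 lower, while Nr4a2 is 320 and 206 in the Nurr1-labelled arrays against 485 and 254 in the controls.

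Other genes differed in the same direction in both pairs without passing the test. On the higher side, Nefm, the medium neurofilament chain, had a mean log2 difference of 1.61 (1.79 and 1.44 in the pairs; adjusted p = 0.0853). En1, a homeobox factor of midbrain dopaminergic neurons, had 1.38 (1.35 and 1.40; adjusted p = 0.0853), and Col3a1, a fibrillar collagen chain, 1.58 (1.96 and 1.20; adjusted p = 0.0853), with 1.41 and 0.83 at other probe sets. The hair keratin Krt81 had 1.62 (adjusted p = 0.0644), the linker histone H1f2 1.39 (0.0853), the matricellular Wnt target Ccn4 1.41 (0.0853), the stress-induced factor Atf3 1.28 (0.134; 0.92 at another probe set) and the secreted glycoprotein Stc2 1.16 (0.144). Ift46, an intraflagellar transport protein, had 1.67 at 1 probe set and -0.05 at the other. On the lower side, Igfbp3, which binds insulin-like growth factors, had -1.69 in each pair (adjusted p = 0.0637) and a mean of -1.05 at another probe set, and the G protein signalling regulator Rgs14 -1.53 (0.0637). Cdkn2a, which encodes cell cycle inhibitors often lost in immortal cells, had -1.65 (-1.64 and -1.65; adjusted p = 0.107). The metalloprotease Adam12 had signals at the floor in both Nurr1-labelled arrays and was at least 5.31-fold and 4.26-fold lower in signal in the pairs. The inhibitory G protein subunit Gnai1 was at least 6.34-fold lower in signal in clone 42, which was at the floor, and 3.15-fold lower in clone 48. On clone 42 the floor lies under the highest control not spiked in (62.7), so the bounds there do not hold for the amount of transcript. The fitted means of Adam12 and Gnai1, -2.25 and -2.16, are not bounds. The Traip signal in clone 42 (61.4) and the Ift46 signal in puroD (53.1) lay under the highest control not spiked in on their array (62.7 and 59.1), so their sizes are uncertain. The ubiquitin ligase Traip had -2.05 (-0.77 at another probe set), the sialyltransferase St3gal6 -1.93, Prps1l3 -1.56 and Rcc2 -1.52. The adjusted p of these last 6 genes lay between 0.113 and 0.237, and a second probe set gave -0.08 for Prps1l3 and 0.10 for Rcc2.

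Nefl, Nefm and Tubb3 were the neuronal differentiation genes of the largest difference, and Fabp7 the neural stem and progenitor gene. Of 11 tested neuronal differentiation genes, 4 were higher and 2 lower in both pairs, and 0 passed over all genes with the probe sets used for the list. Their median was 0.10 and 0.50 in the pairs, and 0.36 between the control clones, in puroB over puroD. Adjusted over the list alone, 3 passed: Nefl, the light neurofilament chain, at 1.67 (2.36 and 0.97), Nefm at 1.61 and Tubb3 at 0.92. camera called the list as higher (adjusted p = 0.0262; adjusted p = 0.822 with an estimated correlation), with a mean log2 difference of 0.32 but a median of -0.02. Of 12 neural stem and progenitor genes, 8 were lower and 1 higher in both pairs; camera called the list as lower (mean -0.44, adjusted p = 0.0109; adjusted p = 0.822 with an estimated correlation). Fabp7, the brain fatty acid-binding protein of radial glia, had -2.24 ± 0.40 (SE; -1.20 and -3.29; limma adjusted p = 0.0503) and was the 1 member that passed over the list alone. The receptor Notch2 had -0.67 and Id2, an inhibitor of differentiation factors, -0.57. Without clone 42 neither list was called (means 0.052 and -0.43), nor without puroD (0.11 and -0.34). The actin and Gapdh 3' to 5' ratios were higher in the same arrays.

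Of 6 tested dopaminergic neuron genes, 4 were higher and 1 lower in both pairs, and camera did not call the list (mean 0.23, adjusted p = 0.0947). Its median was 0.39 and 0.19 in the pairs, and 0.49 between the control clones, in puroB over puroD. The list was called without clone 48 (0.58), without puroB (0.40) or with the filter on all 4 arrays (0.63), and its mean was -0.11 without clone 42. Adjusted over the list alone, 3 passed: En1 at 1.38, the neurotrophin Bdnf at 0.93 (1.62 and 0.24), and Gfra1, the GDNF co-receptor, at -1.46 with clone 48 at the floor. Among NR4A receptors and RXR partners, Nr4a1 had -0.85 (-0.74 and -0.96) and was the 1 of 4 to pass over the list alone, Rxrb had 0.62, and the list was not called (mean -0.19, adjusted p = 0.575). Of 5 astrocyte genes, 3 were lower in both pairs, with the gap junction gene Gja1 at -0.72 and Cd44 at -0.71 (list mean -0.19, adjusted p = 0.568). Of 4 oligodendrocyte genes, Pdgfra, a receptor of oligodendrocyte precursors, had -0.06 and, with clone 48 at the floor, -2.39, and the myelin gene Mbp had -1.22 and -0.63 (list mean -0.36, adjusted p = 0.675). The 4 microglia and macrophage genes gave a mean of -0.24 (adjusted p = 0.599), with the complement gene C1qb at -0.64 and Cd14 at -0.36. The 1 tested endothelial gene, Eng, had -0.24, and the 1 tested retinoid pathway gene, Rdh11, -0.11.

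Fibroblast and mesenchymal genes and growth factor and cytokine genes had positive list means. Of 12 fibroblast and mesenchymal genes, 10 were higher in clone 42 than in puroB (median log2 0.88) and 7 in clone 48 than in puroD (median 0.21). camera called the list as higher (mean 0.40, adjusted p = 0.000771; adjusted p = 0.822 with an estimated correlation). Over the list alone 5 passed: Col3a1 at 1.58, Col1a2 at 1.15 (2.36 and -0.07; -0.025 at another probe set), Col6a2 at 1.00, the transcription factor Snai2 at 0.98 and Twist1, another mesenchymal factor, at -1.21, with a signal in clone 42 (53.9) under the same control level (62.7). Of 14 growth factor and cytokine genes, 7 were higher and 2 lower in both pairs. The list was called as higher by camera (mean 0.35, adjusted p = 0.0153, or 0.822 with an estimated correlation). In puroB over puroD its median was 0.30, larger than the 0.13 and 0.26 of the matched pairs. Over the list alone, the chemokines Ccl7 (2.53; 4.57 and 0.49) and Ccl2 (1.35; 2.11 and 0.60) and the neurotrophic factor Gdnf (0.84) passed as higher, and the angiogenic factor Vegfa (-1.18) and Tgfb3 (-0.84) as lower. Without clone 42 neither list was called (means 0.25 and -0.047), and the growth factor list was also lost without puroD (0.18) and without the pair as a block (0.35, adjusted p = 0.0631). Of 14 axon guidance and cell adhesion genes, 9 were lower in both pairs (mean -0.13, adjusted p = 0.568); the semaphorin Sema3e had 1.33 and passed over the list alone, and the laminin receptor chain Itga6 had -0.86. The 15 Wnt pathway genes gave a mean of 0.013 and a median of -0.04 (adjusted p = 0.748), with Ccn4 at 1.41, which passed over the list alone, and the receptor Fzd7 at -0.63.

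Most cell cycle genes tested were lower in clone 42 than in puroB. Of 22 mitosis genes, 20 were lower in clone 42 than in puroB (median log2 -0.92) and 13 in clone 48 than in puroD (median -0.04). Top2a, the topoisomerase of dividing cells, had -1.72 and -0.64, cyclin Ccnb2 -1.61 and -0.47, and the ubiquitin ligase component Ube2c -1.48 and -0.49. Of 21 S phase and DNA replication genes, 18 were lower in clone 42 (median -0.88) and 10 in clone 48 (median 0.06), with the replication licensing genes Mcm2 at -2.04 and 0.34 and Cdc6 at -1.61 and -0.03, and the polymerase gene Pola1 at -1.61 and -0.02. camera called both lists as lower over both pairs, with means of -0.48 (adjusted p = 1.55e-05) and -0.39 (adjusted p = 0.000771); with an estimated correlation both had an adjusted p of 0.822, and 0 members passed alone. Without clone 42 the means were 0.12 for mitosis and -0.021 for S phase genes, Mcm2 was 0.0145 and neither list was called, and the mitosis list was also lost without puroD (-0.31). The D cyclins and cell cycle inhibitors, 13 tested, were not called by camera (mean -0.14, adjusted p = 0.675) but were called as lower by fry (adjusted p = 0.0454); over the list alone Cdkn2a passed at -1.65 and the growth arrest gene Gadd45b at 1.03 (-0.37 without clone 42 and -0.22 without puroD; 0.89 at another probe set).

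The list of cholesterol synthesis genes had a positive mean and that of glycolysis and hypoxia genes a negative one. Of 12 cholesterol synthesis genes, 7 were higher and 1 lower in both pairs (medians 0.72 and 0.13), with the sterol oxidase Msmo1 at 1.10 and squalene synthase Fdft1 at 1.02, which both passed over the list alone, and Idi1 at 0.78 (1.60 and -0.04). camera called the list as higher (mean 0.42, adjusted p = 0.000771; adjusted p = 0.822 with an estimated correlation). The same genes also differed between the control clones, with a median of 0.83 in puroB over puroD. Of 17 glycolysis and hypoxia genes, 11 were lower and 1 higher in both pairs, and camera called the list as lower (mean -0.39, adjusted p = 0.00432; adjusted p = 0.822 with an estimated correlation). Between the control clones the median of this list was 0.35 in puroB over puroD, as large as the medians of -0.33 and -0.20 in the pairs. Pdk1, which restrains entry of pyruvate into mitochondria, had -1.76 (-3.14 and -0.38) and was the 1 to pass over the list alone; Vegfa had -1.18 and the phosphofructokinase Pfkl -0.81. Without clone 42 neither list was called (means -0.22 and -0.39, Idi1 -0.20); the cholesterol list was also lost without puroD (0.084) and the glycolysis list without puroB (-0.21).

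The remaining lists were not called. The 29 antioxidant and oxidative stress genes had a mean of 0.00066 and a median of -0.04 (adjusted p = 0.748), with 4 higher and 4 lower in both pairs, the pentose phosphate enzyme Taldo1 at 0.65 and the glutathione transferase Gstm2 at 0.41. The 18 apoptosis genes had a mean of -0.12 (adjusted p = 0.575), with Bnip3 at -0.68 and the initiator caspase Casp8 at -0.58. The 21 heat shock and unfolded protein genes had a mean of -0.03 (0.0046 with scaling to the median), a median of 0.02 and an adjusted p of 0.951; Atf3, at 1.28, passed over the list alone and the disulfide isomerase Pdia4 had -1.01 in the first pair. The 9 interferon response genes had a mean of -0.03, which was 0.028 after quantile normalization, and a median of 0.07 (adjusted p = 0.803), with the peptide transporter Tap1 at -0.81 and Ifi27 at 0.30. The 20 mitochondrial respiration genes had a mean of 0.05 (adjusted p = 0.575; called without puroD, at 0.20), with Sdhc of complex II at 0.54 and cytochrome Cyc1 at -0.38. The 9 ribosomal protein genes had a mean of -0.0056 (0.031 with scaling to the median) and a median of 0.03 (adjusted p = 0.833); Rps29 had 0.08 and -0.48 in the pairs and Rpl13a 0.79 and -0.51.

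**Figure D2:**
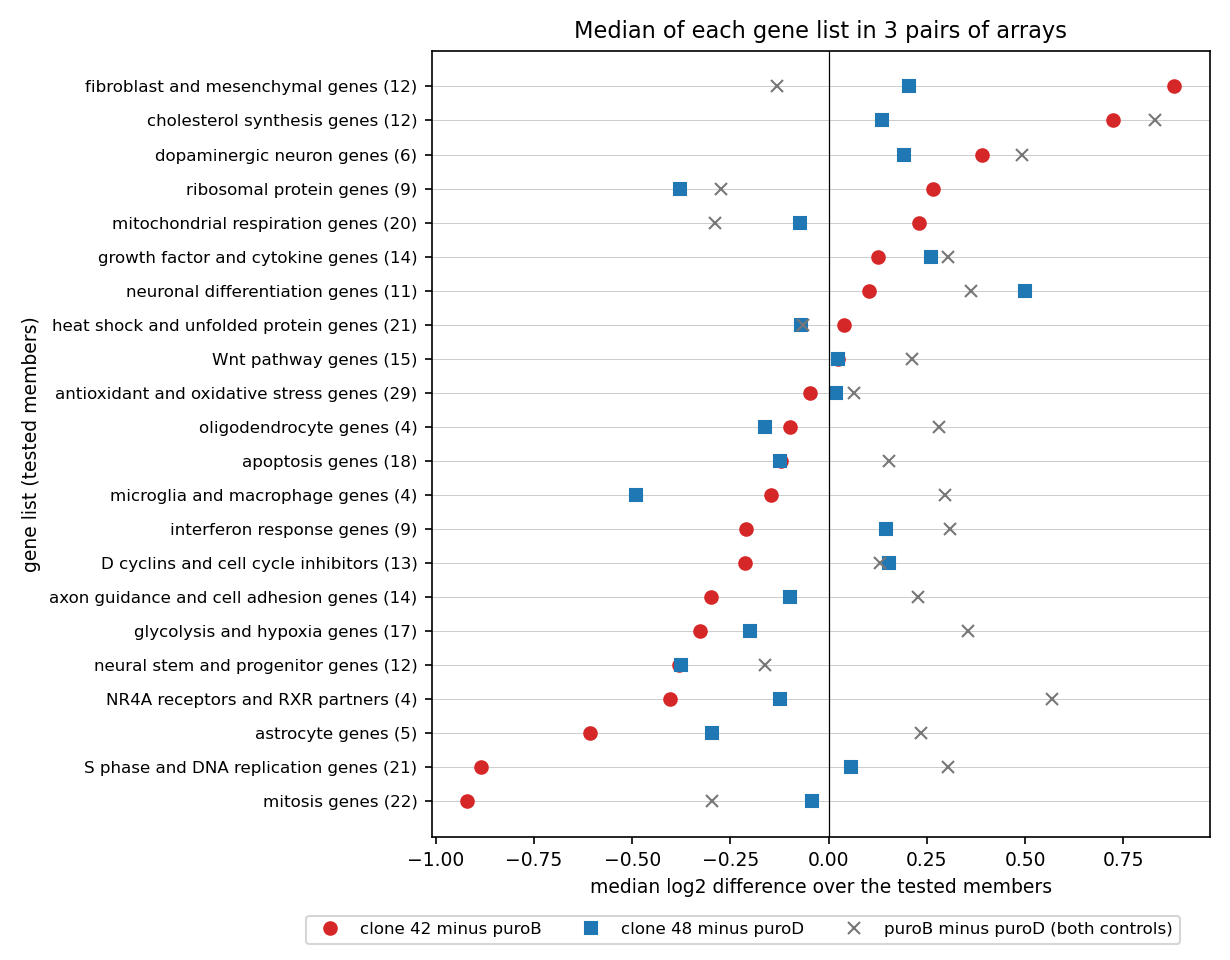
Median log2 difference of each list with at least 2 tested members (number tested in brackets) in clone 42 minus puroB (red circles), clone 48 minus puroD (blue squares) and between the controls, puroB minus puroD (grey crosses). Mitosis and S phase genes lie at -0.92 and -0.88 in the first pair and at -0.04 and 0.06 in the second, and cholesterol synthesis genes lie at 0.83 between the controls.

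In clone 42 against puroB, 536 of 6419 tested probe sets differed by 2-fold or more, 229 higher and 307 lower in clone 42. The share of higher probe sets was 42.7%, 51.4% after quantile normalization and 52.5% with scaling to the median. The highest ratios were those of the chemokine Ccl7 (log2 4.57; signals 2364 and 99.7), Tnc (4.04), the aldo-keto reductase Akr1c13 (3.92), the histone gene H3c14 (3.82) and the interferon-inducible Ifi202b (3.19). The lowest were those of Sox11, a transcription factor of neural progenitors and immature neurons (-4.16; signals 74.6 and 1330), Limch1 (-3.28, clone 42 at the floor), the actin-associated Pdlim4 (-3.15), Pdk1 (-3.14) and Col11a1 (-2.95, clone 42 at the floor). The medians of the mitosis and S phase lists lay below all 10000 random lists, and those of the fibroblast and cholesterol lists above all of them. With 1 array per clone these differences have no replicate check.

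In clone 48 against puroD, 346 probe sets differed by 2-fold or more, 107 higher and 239 lower in clone 48. The highest ratios were those of the small GTPase Rhou (log2 2.56), the recombinase gene Rag1 (2.35), Fbxw4 (2.14), the semaphorin Sema6c (2.11, with 2 of its 4 arrays at the floor) and Ift46 (1.98). The lowest were those of Fabp7 (-3.29; signals 157 and 1537), Ptgr1, a reductase of prostaglandins and leukotrienes (-3.14, clone 48 at the floor), Akr1c13 (-3.04), the melatonin synthesis enzyme Aanat (-2.90) and Sgip1 (-2.90, clone 48 at the floor). The median of the neuronal differentiation list lay at percentile 99.9 and that of the ribosomal protein list (-0.38) at percentile 0.795; after quantile normalization the latter median was -0.084. The puroD signals of Rhou, Rag1 and Ift46, 49.6, 43.5 and 53.1, lay under the highest control not spiked in on that array, 59.1, so the sizes of these ratios are uncertain. The share of higher probe sets was 30.9%, 44.2% after quantile normalization and 42.2% with the filter on all 4 arrays.

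The pairs shared a small part of these differences. At 2-fold or more, 70 probe sets differed in the same direction in both pairs, 21 higher and 49 lower, where 15.2 are expected of independent lists (n1 × n2 / N per direction), and 25 differed in opposite directions, where 13.6 are expected. Across all tested probe sets, which are not independent replicates, the log2 differences of the pairs correlated with r = 0.09 (Spearman 0.06). Grouping the arrays the other way, by clone 42 minus clone 48 and puroB minus puroD, gave 85 probe sets in the same direction (20.9 expected) and r = 0.19. With the pairs crossed, clone 42 minus puroD and clone 48 minus puroB, 58 probe sets differed in the same direction (28.4 expected) and 75 in opposite directions (27.7 expected), and r turned to -0.11 (Spearman -0.13).

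**Figure D3:**
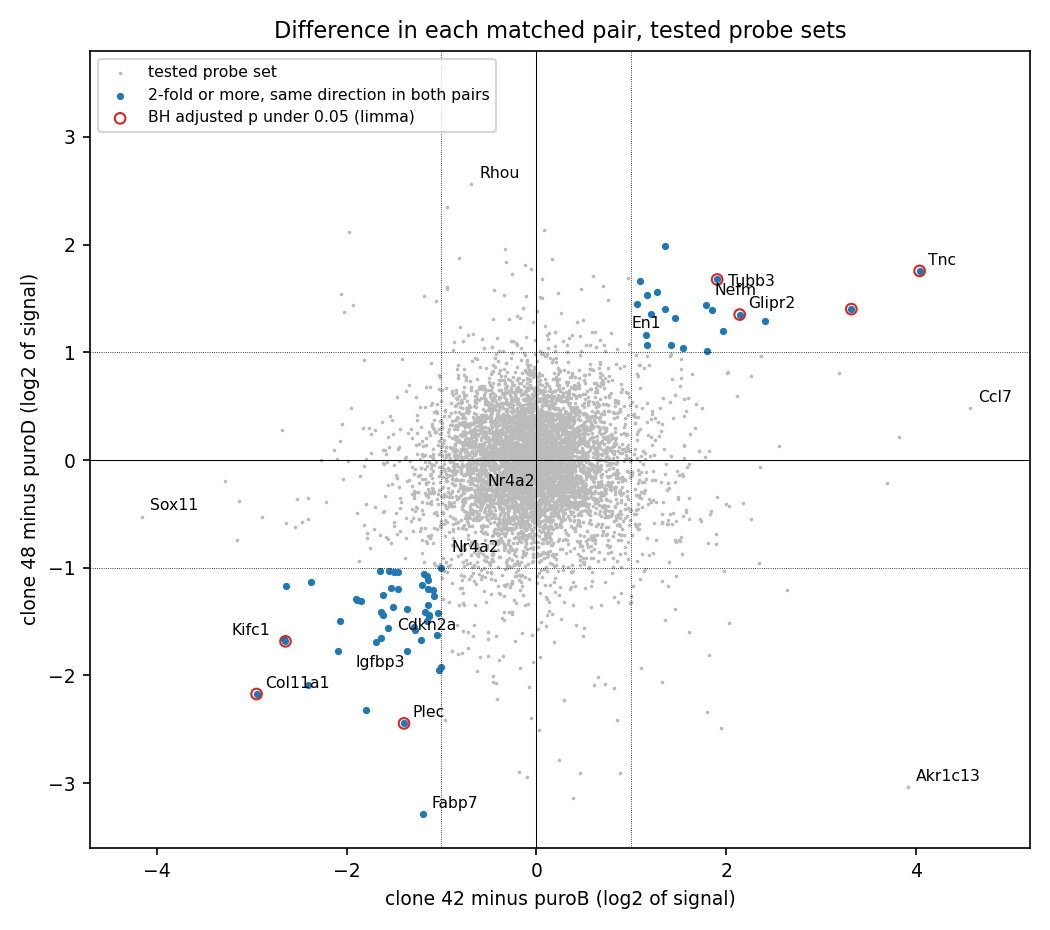
Log2 difference of signal in clone 42 minus puroB (horizontal) and clone 48 minus puroD (vertical) for each tested probe set; blue points differ by 2-fold or more in the same direction in both pairs and red rings mark the 7 that passed in limma. Tnc, at 4.04 and 1.76, and Fabp7, at -1.20 and -3.29, stand out from the cloud, and Akr1c13 lies at 3.92 and -3.04.

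Control clones that carry the same empty vector give a view of differences between clones. Because they belong to different matched pairs, their difference also holds any difference between the pairs. Between puroB and puroD, 389 probe sets differed by 2-fold or more, 194 higher and 195 lower in puroB. The highest in puroB were Rhou (log2 2.78), the quinone reductase Cryz (2.70), Rag1 (2.60), the deubiquitinase Usp15 (2.57) and Gadd45b (2.50), and the lowest were Akr1c13 (-2.67), the ATPase Vcp (-2.48), the mitochondrial co-chaperone Dnajc15 (-2.28), Gt(ROSA)26Sor (-2.23) and the neuropeptide gene Hcrt (-2.21, with puroB at 44.3, just above the floor). The puroD signals of Rhou, Cryz, Rag1 and Usp15, and the puroB signal of Hcrt, lay under the highest control not spiked in on their array (59.1 and 49.8), so these sizes are uncertain as well. The share of higher probe sets was 49.9%, and 38.7% after quantile normalization or 39.4% with scaling to the median. Between clone 42 and clone 48, 689 probe sets differed by 2-fold or more, 395 higher and 294 lower in clone 42. The mitosis genes had a median log2 difference of -1.24 between these clones, the cholesterol synthesis genes 1.41 and the growth factor and cytokine genes 0.76.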

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

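The tests in this part were chosen after the results were seen. Several genes went opposite ways in the 2 matched pairs, which drew attention to them because each pair compares a Nurr1-labelled clone with its control. With 1 array per clone the difference between the pairs was not tested. Akr1c13 had a log2 difference of 3.92 in clone 42 against puroB and -3.04 in clone 48 against puroD, 6.96 apart. Hcrt had 1.80 and -2.34, 4.14 apart, with clone 48 at the floor. Sema6c had -1.98 and 2.11, -4.09 apart, with clone 42 and puroD at the floor. Gt(ROSA)26Sor had 1.33 and -2.06, 3.39 apart, and Dnajc15 1.98 and -1.03, 3.004 apart. For each of these genes the control clones also differed by 2-fold or more, from -2.67 for Akr1c13 to 1.98 for Sema6c in puroB over puroD. All 9 ribosomal protein genes were higher in clone 42 than in puroB and all 9 lower in clone 48 than in puroD, with medians of 0.26 and -0.38, 0.64 apart. After quantile normalization the gap was smaller, with medians of 0.17 and -0.084. It stayed with scaling to the median (0.34 and -0.38) and with the deposited values (0.26 and -0.38).

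The first pattern weighed is that Nr4a2 was not higher in the Nurr1-labelled clones. An exchange of labels between the groups would put the signal of the control-labelled arrays above that of their matches. All 4 within-pair differences had this direction, at -0.60 and -0.30 for 1 probe set and -0.98 and -0.91 for the other, whose unadjusted p was 0.0151 in limma (adjusted p = 0.453). An exchange was asked to give a 2-fold difference or more in all 4, and this was not met. The excess of the control-labelled array ran from 0.30 to 0.98 on the log2 scale. The largest was too close to 2-fold to speak against an exchange. An exchange cannot be told apart from a lower endogenous level under correct labels, because it is not known whether the probes see the transgene. If the probes lay outside the transfected sequence, no gain would be seen, and 0 of 2 probe sets were 2-fold or more higher in both Nurr1-labelled clones. That also cannot be told apart from a transgene that was lost or weakly expressed, because the probe positions and the transfected sequence are not given in the sources used here. Effects of Nurr1 and differences between clones both remain open for each gene named.

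The second pattern is the lower level of cell cycle genes in clone 42. Array scaling is argued against for mitosis genes, because their median lay -0.89 from that of all probe sets after quantile normalization; scaling by 1 factor per array cannot move this difference and was not counted as a test. A high level in puroB compared with clone 48 and puroD, as the whole cause, is argued against by the differences that leave puroB out. These differences also hold any difference between the matched pairs. They therefore cannot tell a low level in clone 42 from a puroB level that is high only for its pair. The mitosis list median was -1.24 in clone 42 against clone 48 and -1.27 against puroD (SE of the weaker over genes 0.12), and puroB itself was -0.30 against puroD. For S phase genes the medians were -0.82 and -0.62 (SE over genes 0.12); since puroB was 0.30 above puroD, a part of their difference may come from puroB. These errors hold no spread between arrays of a clone. Per the labels the pairs were matched on proliferation rate. What stays open is slower growth of clone 42 at harvest, a property of this clone, or a puroB level high for its pair. An effect of Nurr1 at a level that clone 48 did not have also stays open. Culture details beyond proliferating conditions are not given in the sources used here.

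The third pattern is the level of cholesterol synthesis genes, which was higher in clone 42 and puroB than in clone 48 and puroD. Array scaling is argued against, because the smaller of both list medians lay 0.79 above that of all probe sets after quantile normalization. A single deviating array is argued against, because it can move only 1 of 2 differences that share no array, and the list median was 1.41 in clone 42 over clone 48 and 0.83 in puroB over puroD (SE of the smaller over genes 0.19). The signs of RNA integrity follow the same split: the actin 3' to 5' ratio was 1.68 and 1.51 in clone 42 and puroB against 2.41 and 2.0 in clone 48 and puroD, and that of Gapdh 0.935 and 0.859 against 1.24 and 0.973. RNA quality therefore stays open and was not tested. A difference in medium or serum, density or day of harvest between the pairs could give this pattern and remains untested, as does a biological difference between clones of different proliferation rate.

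At 2-fold or more, 70 probe sets differed in the same direction in both matched pairs. Of the 3 ways to split 4 arrays into 2 and 2, 2 gave as many, and the highest other split gave 85. The splits are too few for a share under 0.05. The higher split sets clone 42 and puroB against clone 48 and puroD, so it follows the matched pairs; the fit with the pair as a block removes this difference and called 7 probe sets.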

How the results depend on the processing

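The alternatives were chosen before the data were examined. Among named genes, 963 values under alternatives kept their direction and side of the threshold, 51 lost a call, 37 gained 1 and 13 reversed. Since only 7 probe sets were called in the main fit, most of the 963 belong to genes without a call there. All 51 losses fall on the few called genes, so these totals do not show that the calls are stable. Among lists the numbers were 300, 36, 5 and 32. Unless a cause is named, the cause was not tested.

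The count of called probe sets, 7, was 0 without the pair as a block, with quantile normalization, with scaling to the median, with no floor and with no filter. The log2 differences ran from 2.90 to 3.04 for Tnc, 1.77 to 1.83 for Tubb3 and 1.75 to 1.79 for Glipr2. They ran from -1.92 to -1.85 for Plec and -2.16 to -2.06 for Kifc1. Leaving out the pair, the floor or the filter could not move these values, so only quantile normalization and scaling to the median tested them. Col11a1, with clone 42 at the floor, ranged from -3.35 with no floor to -2.36. The limma adjusted p-values of all these genes were 0.0625 to 0.0681 with no floor, 0.0662 to 0.0759 with scaling to the median, and 0.365 to 0.903 under the others. There were 8 calls with the deposited values, all 7 among them, and 7 without an intensity trend, 3 of them shared. Without the trend 1 was higher and 6 lower. Among the calls lost there were Tubb3, Glipr2 and Plec, with limma adjusted p-values from 0.069 to 0.078. The count was 17 with a floor at the median (6 shared), 49 with all 4 arrays above the median (4 shared) and 14 with 1 probe set per gene (5 shared), where fewer probe sets are tested in the last 2. With the floor at the median Col11a1 was -1.03 and lost its call (limma adjusted p = 0.0998). With 1 probe set per gene another probe set stood for Ift46 (-0.050) and Rcc2 (0.10), which reversed both.

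Of the 8 list calls, 0 held with an estimated correlation, with the same list means and an adjusted p of 0.822: -0.44 for neural stem, 0.32 for neuronal differentiation, 0.40 for fibroblast, -0.39 for S phase, -0.48 for mitosis, 0.35 for growth factor, 0.42 for cholesterol and -0.39 for glycolysis genes. With fry these means had adjusted p-values between 0.663 and 0.711, and 1 list was called, D cyclins and cell cycle inhibitors (-0.14, adjusted p = 0.0454). The growth factor list also lost its call with the mean of a gene's probe sets (0.30, adjusted p = 0.0848) and without the pair as a block (0.35, adjusted p = 0.0631).

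With no filter 1 list, mitosis, was called, where genes near background enter the lists. The others were -0.36 for neural stem, 0.23 for fibroblast, -0.37 for S phase, 0.15 for growth factor, 0.34 for cholesterol and -0.37 for glycolysis genes, and neuronal differentiation (-0.011), antioxidant (-0.017) and Wnt genes (-0.022) reversed. With all 4 arrays above the median, dopaminergic genes were called (0.63), neuronal differentiation genes were not (0.16), and antioxidant (-0.0080) and interferon genes (0.073) reversed. Interferon genes also reversed with quantile normalization (0.028), scaling to the median (0.010) and a floor at the median (0.044). Heat shock (0.0046) and ribosomal protein genes (0.031) reversed with scaling to the median, and oligodendrocyte genes with a floor at the median (0.041).

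At 1.5-fold the counts were 1709 for clone 42 against puroB, 1259 for clone 48 against puroD, 1431 between controls, 1962 between Nurr1-labelled clones and 282 in the same direction in both pairs; at 3-fold they were 123, 85, 78, 171 and 10. With no filter they were 966, 681, 775, 1085 and 125, since more probe sets are counted. A floor at the median gave 215 for clone 48 against puroD and 44 in both pairs. With all 4 arrays above the median there were 154 for clone 48 against puroD, 244 between controls, 434 between Nurr1-labelled clones and 28 in both pairs.

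Leaving out 1 clone sets 1 array against 2, without the pair, and assumes that the lone array varies like the others. Called probe sets ranged from 0 to 51 and called lists from 0 (without clone 42) to 9 (without clone 48), with 4 without puroD. List means ranged from -0.54 to -0.34 for neural stem, 0.052 to 0.59 for neuronal differentiation, 0.25 to 0.54 for fibroblast, -0.76 to -0.021 for S phase, -1.08 to 0.12 for mitosis, -0.047 to 0.74 for growth factor, -0.22 to 1.06 for cholesterol and -0.58 to -0.21 for glycolysis genes. Among lists not called, they ranged from -0.11 to 0.58 for dopaminergic, -0.47 to 0.087 for NR4A, -0.48 to 0.096 for astrocyte, -0.51 to 0.034 for microglia, -0.33 to 0.057 for D cyclin, -0.036 to 0.037 for antioxidant, -0.11 to 0.13 for Wnt, -0.29 to 0.033 for axon guidance, -0.11 to 0.060 for interferon, -0.17 to 0.10 for heat shock, -0.099 to 0.20 for mitochondrial and -0.20 to 0.19 for ribosomal protein genes. Single genes that reversed ranged from -0.92 to 0.016 for Nr4a2, -1.72 to 0.0145 for Mcm2, -0.37 to 2.44 for Gadd45b, -0.47 to 1.06 for Ifi27, -0.20 to 1.77 for Idi1, -0.30 to 0.58 for Rpl13a, -2.46 to 0.0074 for Pdgfra, -0.79 to 0.065 for Cd14 and -0.37 to 0.15 for Rdh11. Signals near background limit the folds of the genes marked above as at the floor or uncertain. Since the floor is the 30th percentile, between 27.8% and 33.0% of all probe sets lay at it in each array by construction. Among tested probe sets the share was between 0.062% (puroB) and 0.218% (clone 42).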

Other observations

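The genes in this part were chosen after their values were seen, and no explanation was tested for them. Tfrc, the transferrin receptor that takes up iron, was lower in the Nurr1-labelled clone of both pairs at all 5 of its probe sets, 3 of which are array controls. The log2 differences were -0.67 and -1.63 at 1 gene probe set and -0.15 and -0.73 at the other, with adjusted p-values of 0.225 and 0.895 in limma. The controls gave -0.83 and -1.94 at the 3' end, -0.69 and -1.81 at the 5' end, where clone 48 was at the floor, and -1.15 and -1.96 in the middle, where clone 48 was also at the floor.

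Histone probe sets did not move together. Of 9 tested, 3 were higher and 2 lower in both pairs. H3c14 had 3.82 and 0.22, H1f2 1.47 and 1.32, and the probe set shared by 3 histone H2B genes 3.32 and 1.40, whereas H2bc21 had -1.05 and -1.62 and H1f10 -0.81 and 1.24.

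Fos, a growth factor-induced transcription factor gene, had a log2 difference of 1.87 in puroB over puroD and 3.24 in clone 42 over clone 48. A probe set of Fos too dim to be tested had -0.16, with puroB at the floor, and 0.40, with clone 48 at the floor. Its partner Jun had 1.54 and 0.42 in these comparisons, and Gadd45a 1.31 and 2.31. Atf3 had 1.87 and 1.72 at 1 probe set and 0.97 and 2.02 at another, and Gadd45b 2.50 and 2.81 at 1 and 1.43 and 1.07 at another. Ccn4 had 1.70 and 1.41. These genes form no list fixed beforehand, and they were not tested as a group.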
